A study of Mus musculus with 6 samples.

How the data were processed

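RNA sequencing was applied to tissue from the ischaemic penumbra of C57BL/6J mice, in 6 samples. Per the labels' protocols, RNA was extracted with the mirVana kit and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps strand. Per the submitters' processing notes, cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and DESeq2 were used, and the genome build was mm9. The role and settings of each tool, the version of DESeq2 and the gene annotation are not given in the sources used here.

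The deposited data are 1 table for the whole series, with 1 row per gene. Per the file headers, it holds a count column and a second column headed PFKM for each of 6 sample names, followed by annotation columns. The 6 sample names are running numbers. A search of every label of the 6 samples for these names found 0 of them, and the titles name the samples only by treatment and a number. Column order and the values in a column are no evidence of what a sample received, so no column was given to a sample or to a group. All 12 per-sample columns were therefore used for no result; they were read only to see what kind of values they hold. For the same reason, no total count could be given for a named sample. Totals of the numbered columns, which need no such key, were not computed, so depth and its precision are not reported.

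The samples were grouped by their titles, before the data were examined, into 3 vehicle and 3 gelsevirine samples. The comparison planned at that point was a test of gene counts between the groups, with set tests over fixed gene lists. Of the 42 lists, the sex-linked one was a label check and was to stay out of the set tests. Other normalizations, filters, tests, a replicate block and the omission of single samples were planned as alternatives. None of these tests and alternatives was run. The rule for naming genes, fixed at the same time, took the genes with the strongest changes, members of the lists that changed and a short set of STING, cytokine and glial genes. Without a test it selects only that short set, and no values are given for it. The genes absent from the table that are named in the report were chosen after the table was seen.

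What was computed comes from the gene symbols and annotation columns alone, read with Python 3.11.15 and pandas 2.3.3. The symbols were matched, exactly and with a few alternative symbols, to the fixed lists. NCBI gene identifiers and RefSeq transcript accessions were matched to a RefSeq gene table of another assembly, GRCm38.p6, which was used only for names and biotypes. No coordinates are given, since that assembly differs from the build in the processing notes.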

Results

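The series profiled gene expression in the ischaemic penumbra, the rim of tissue around the core of a stroke, in brains of C57BL/6J mice. The treatment labels name MCAO, the abbreviation in use for middle cerebral artery occlusion, an experimental model of ischaemic stroke. The 6 samples fell into 2 groups by their titles, with 3 samples labelled as vehicle and 3 as gelsevirine at 10 mg/kg. Gelsevirine is an alkaloid of Gelsemium plants. The design implies 1 comparison, gelsevirine against vehicle, which asks which genes differ in the penumbra of treated mice.

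That comparison was not made. The per-sample columns of the deposited table carry running numbers, and 0 of the 6 names occur in the labels of any sample. No measured value could be tied to vehicle or to gelsevirine, so no fold change, level, error or p-value is reported for any gene. Nothing is stated here about an effect of gelsevirine, whether present or absent.

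The table listed 21878 genes, each with a distinct symbol. All of them had an NCBI gene identifier, but whether the identifiers were distinct was not examined. Gene Ontology terms were attached to 20677 of them (94.5%). A pathway entry was attached to 7874 genes (36.0%) and a transcription factor family to 1368 (6.25%). These counts describe the annotation and carry no information on expression.

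Of 739 distinct genes in the 42 lists fixed for this tissue and treatment, 719 were listed in the table. Of these, 4 were listed under an older symbol than the one in their list. The lists' own symbols were not all current, Atp5b among them, so the 4 are not all the genes listed under an older symbol. All members were listed for 37 of the 42 lists. A listed gene is one that the annotation names, and its listing carries no information on expression in the penumbra. The RefSeq gene table held 21900 protein-coding genes, and 21406 genes of the deposited table matched that biotype. Near-complete lists therefore reflect the breadth of the annotation. The cGAS-STING list was named for a cytosolic DNA sensing pathway that leads to interferon production, but also held genes such as Mavs and Ticam1. It had 15 of 15 members, with Sting1 listed as Tmem173 and Cgas as Mb21d1. The kinase Tbk1, the transcription factor Irf3 and the interferon gene Ifnb1 were listed under their own symbols. The list of inflammatory cytokines and NF-kB targets had 36 of 36 members, among them Tnf, Il1b and Il6. The list for activated or phagocytic microglia had 26 of 26, including Aif1, and that for neurons in general had 18 of 18.

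The other 5 lists were incomplete. The type I interferon list had 40 of 42 members and lacked Mx1 and Mx2. The lymphocyte list had 19 of 22 and lacked the receptor constant-region genes Trac and Trbc2 and the immunoglobulin heavy chain gene Ighm. The reactive astrocyte list had 27 of 28, with the intermediate filament gene Gfap listed and Chi3l1 found only by its NCBI gene identifier, not by that symbol. The list of mitochondrially encoded genes had 0 of 13 members. The sex-linked list had 4 of 5 and lacked Xist, the long noncoding RNA of X inactivation. A gene that is not listed has no value here, which differs from a gene counted at 0.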

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

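No result of a test is reported, so none depends on a processing choice. The alternatives chosen before the data were examined were not run, because each needs columns tied to groups: DESeq2 size factors and upper-quartile factors, looser and stricter filters on low counts, the DESeq2 and limma-voom tests, other thresholds, an estimated correlation and fry for the gene lists, and the omission of each sample. No paired analysis was possible because the table's columns carry no replicate number of the labels. A key from the numbered columns to the sample titles would allow the comparison to be run as planned. The number of list genes found in the table was 719 of 739. It was 715 with the lists' own symbols alone, and 720 when NCBI gene identifiers were also matched through RefSeq symbols and synonyms. Both alternatives were chosen after seeing the data, and the count of 719 was not planned either. The gene added was Chi3l1.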

Other observations

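The annotation in the table was compared with a RefSeq gene table of assembly GRCm38.p6, while the submitters' processing notes name mm9. Of the 21878 genes, 21727 (99.3%) had an NCBI gene identifier in that table, and 20454 of these (94.1%) had the same symbol in both. A single RefSeq transcript accession was read for each of the 21878 genes. Of these accessions, 19078 (87.2%) were found when the version was ignored and 13175 (60.2%) with the same version. Predicted models, with accessions that begin with XM or XR, made up 8711 of the accessions (39.8%). Other transcripts of these genes were not examined, so this is not the share of genes known only from predicted models. No annotation of mm9 was compared, so these values do not decide which assembly the reads were counted on.

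By the biotypes of the same RefSeq table, 21406 of the 21727 matched genes (98.5%) were protein coding and 114 (0.525%) were long noncoding RNAs. The RefSeq table itself holds 21900 protein-coding genes and 12731 long noncoding RNAs. Of the 19 list genes that were not found by symbol or gene identifier, 13 were mitochondrially encoded. The RefSeq table lists all 13 of these as protein coding, the same biotype as most genes of the deposited table. Of the other 6, Mx1 and Mx2 had the biotype transcribed pseudogene, Trac, Trbc2 and Ighm were constant regions, and Xist was a long noncoding RNA.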
